A study of Danio rerio with 24 samples.

How the data were processed

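RNA sequencing counts of zebrafish (*Danio rerio*) of the transgenic line Tg(fli1:egfp) were analysed from 24 libraries in 6 groups. Animals were kept in the solvent DMSO, tetrahydrocannabinol (THC) or cannabidiol (CBD) through development, and whole embryos at 10 hours post-fertilisation (hpf) or larvae at 96 hpf were taken, with 4 libraries in each group. The labels call these 4 libraries biological replicates and do not say whether they came from separate clutches or tanks, so p-values measure the spread between these samples. Doses and hours of exposure are not given in the sources used here.

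Per the labels' protocols, total RNA was extracted on RNeasy columns with DNase digestion, and TruSeq libraries were sequenced as paired reads on a HiSeq instrument. The deposited values are raw counts of reads per gene, 1 file per library with 35117 Ensembl gene identifiers and no normalization. Per the submitters' processing notes, the steps used STAR, HTSeq and edgeR with the genome build GRCz11. Their versions and the HTSeq settings are not given in the sources used here, so counts of near-identical paralogs, of overlapping genes and of antisense partners are less certain than others. The files held 0 rows that name no gene. Gene annotation was not used here, and no positions are given. Symbols came from a table of gene names that covered 27000 of the 35117 identifiers. Many of its symbols are written in the human style in capitals (*CYP1A1* for zebrafish cyp1a, *FLI1* for fli1a), and 4682 identifiers share their symbol with another.

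Library totals ranged from 14879976 to 29641377 counts in 23 libraries. DMSO library 4 of 10 hpf held 125926 counts, so that 3 counts, taken as the floor of detection, correspond to 23.8 CPM (counts scaled by library size) there and to 0.101 to 0.202 CPM in the others. The floor and the exact Poisson p cover counting error only. No pair of replicates agreed within sampling noise: over the 36 pairs within groups, the lowest chi-square per degree of freedom was 2.53 (genes with a summed count of at least 20), and each library counted as 1 replicate.

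Each stage was fitted apart over its 12 libraries, so that the groups share an estimate of the spread. Genes were filtered with filterByExpr (minimum count 10, minimum total count 15), libraries were scaled by trimmed mean of M values (TMM), and group means were compared with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The comparisons were THC against DMSO, CBD against DMSO and CBD against THC at each stage. The stage difference of each treatment effect was tested as an interaction over all 24 libraries. CPM values are TMM-scaled and given as mean ± SD over 4 libraries, and standard errors (SE) of log2 fold changes were derived from the fold change and its F value. Intervals are 95% intervals from that SE and the degrees of freedom of the fit.

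Lists of genes (40 in all, 916 members written, 877 matched to identifiers) were fixed before the data were examined, as were the comparisons, the tests and the rule for naming genes. Each list with at least 5 tested members was tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted over the lists of the comparison. Camera was run again with a correlation estimated from the data, and fry asked whether a list's genes moved on balance in 1 direction or, in its mixed test, in either. Counts of members past the threshold are also given adjusted over the list alone. Some genes are members of more than 1 list, so the calls of such lists are not independent.

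Genes were named by rule. Among genes past the threshold with a gene name, a mean of at least 1 CPM in either group and no overlap between the 4 libraries of each group, the 8 largest rises and the 8 largest falls were taken. Up to 4 members with the smallest p were taken from each list past the threshold. Where no gene passed, the 5 genes with the smallest p were taken. *CNR1*, *CNR2*, *CYP1A1* and *FLI1* were named in each comparison with DMSO. *PGD*, *nanog*, *MYOD1*, *MYOG*, 2 clone-named genes and *CYP1A1* between CBD and THC fall outside this rule and were chosen after their values were seen.

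Alternatives planned before the data were examined were DESeq2 1.42.0 (its size factors in edgeR, and its own Wald test), no filter, a filter of 1 CPM in 4 libraries, only the 8 libraries compared, the replicate number as a block, a fold of at least 1.5 and leaving out each library in turn. After the library totals and principal components were seen, a fit without DMSO library 4 and CBD library 3 of 10 hpf and a limma voom fit with a quality weight per library were added. The fits were tested on simulated counts with 200 genes changed at once by known folds. Each gene was drawn apart and without the structure of the samples. With fewer changed genes the adjusted threshold is stricter, so the shares recovered may be too high for the real comparisons. The correlation of the THC and CBD effects across genes was set beside 20 simulations of unchanged groups with shared controls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.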

Results

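Transcript levels were measured in whole zebrafish raised in DMSO, THC or CBD, the first being the solvent control, at the close of gastrulation (10 hpf) and in larvae (96 hpf). The series asks what each cannabinoid does to development. THC and CBD are plant cannabinoids built from the same atoms: THC has a closed pyran ring where CBD has an open ring and a free phenol. The line Tg(fli1:egfp) carries a green fluorescent protein under the regulatory sequence of fli1, a gene of blood vessel endothelium. Each of the 6 groups held 4 libraries. Library totals lay between 14879976 and 29641377 counts, except for DMSO library 4 of 10 hpf with 125926 counts, 153.3 times shallower than the median of the other 10 hpf libraries. CBD library 3 of 10 hpf held 20212 genes with a count and 2.78% mitochondrial counts, against 23229 to 24432 genes and 1.53% to 1.97% in the other CBD libraries of that stage. The common biological coefficient of variation was 0.476 at 10 hpf and 0.195 at 96 hpf.

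**Figure D1:**
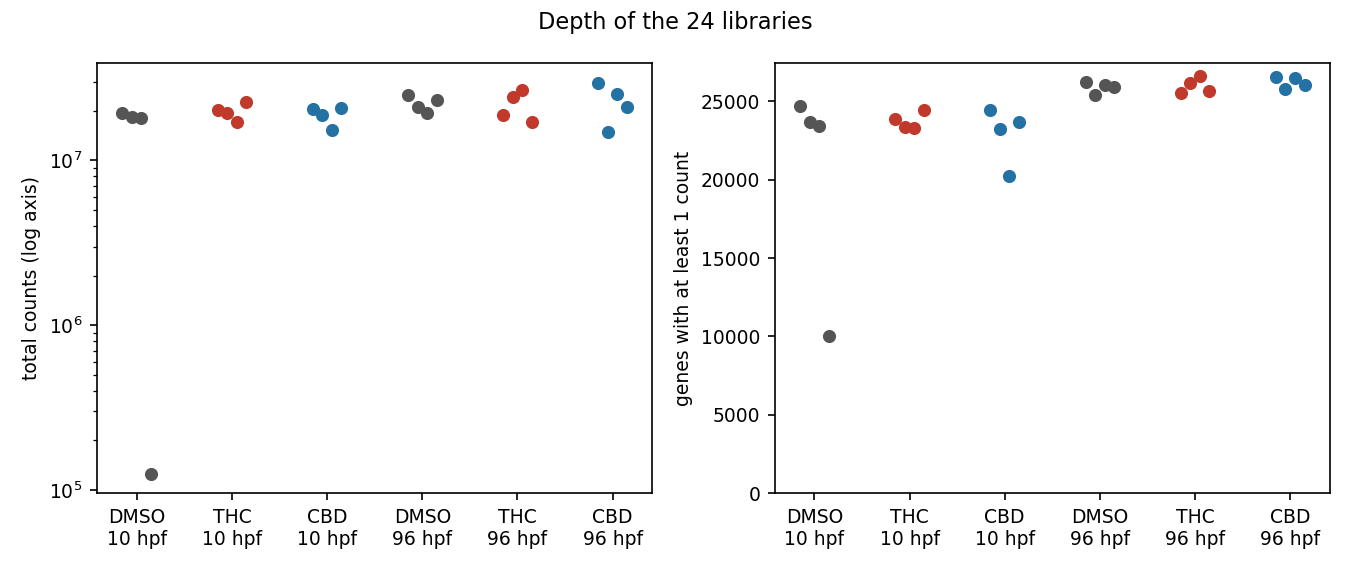
Total counts (left, log axis) and genes with at least 1 count (right) of each of the 24 libraries, by treatment and stage, with 1 point per library. DMSO library 4 of 10 hpf stands apart with 125926 counts and 10045 genes.

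Marker genes looked at after the spread of the 10 hpf libraries was seen, which turn on or off around gastrulation, differed between 10 hpf libraries of the same group. *nanog*, a pluripotency factor of the early embryo, stood at 9.41 CPM in DMSO library 1, 10.2 in THC library 4, 10.0 in CBD library 1 and 11 in CBD library 2, and between 69.7 and 200.3 CPM in the 7 other deep libraries. *MYOG*, which drives muscle differentiation, had 71 counts in DMSO library 1 and 173 in CBD library 1, and at most 1 count in any other 10 hpf library. The slow muscle myosin *smyhc1* stood at 66.6 CPM in DMSO library 1 and 149.3 CPM in CBD library 1. *he1.1*, a hatching enzyme, stood at 60.6 CPM and 152 CPM in the same libraries, at 16.9 CPM in THC library 4 and at 10.6 CPM in CBD library 2. *pvalb1*, a parvalbumin of fast muscle, stood at 242.8 CPM in the shallow DMSO library 4, where it rested on 34 counts. These differences lay within groups, and they stand beside each 10 hpf comparison that follows.

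**Figure D2:**
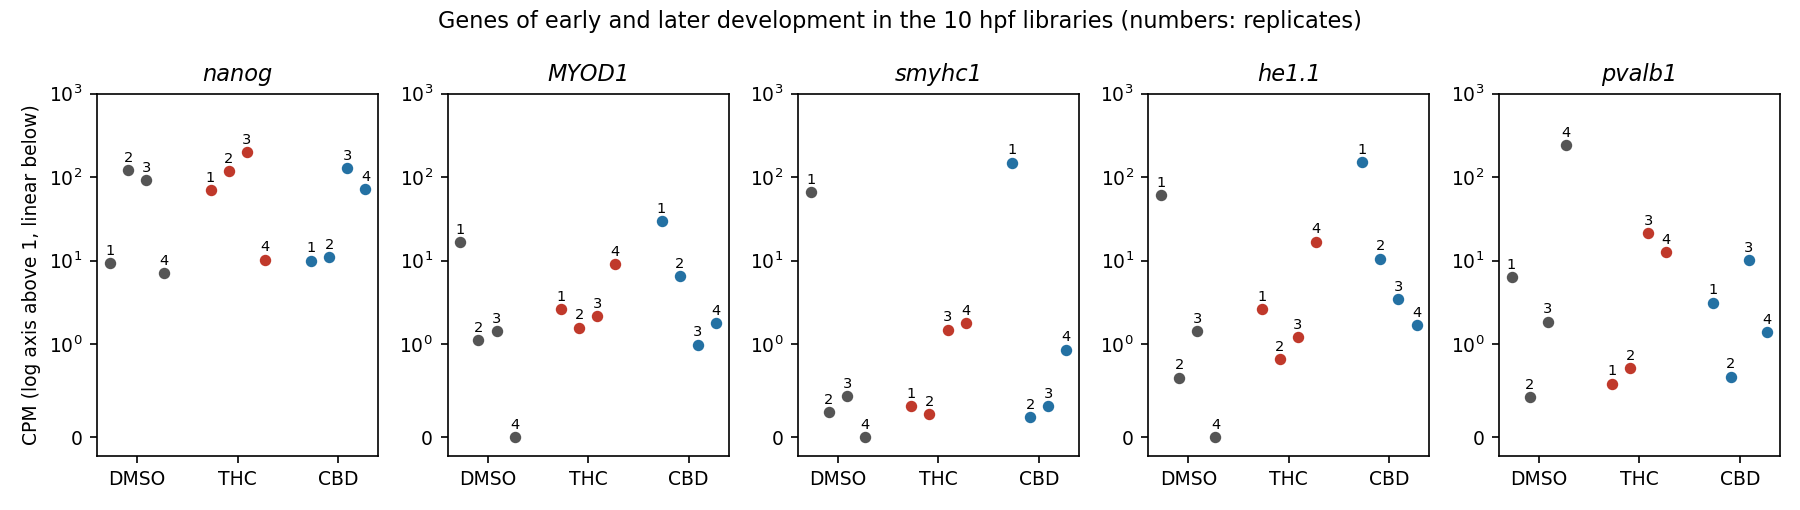
CPM of 5 genes in the 12 libraries of 10 hpf (log axis above 1, linear below), with 1 point per library and replicate numbers beside the points. *nanog* lies near 10 CPM in DMSO library 1, THC library 4 and CBD libraries 1 and 2, where *MYOD1* and *he1.1* lie higher than in the other deep libraries of their group, and in DMSO library 4 a single count is worth about 7.14 CPM.

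**Figure D3:**
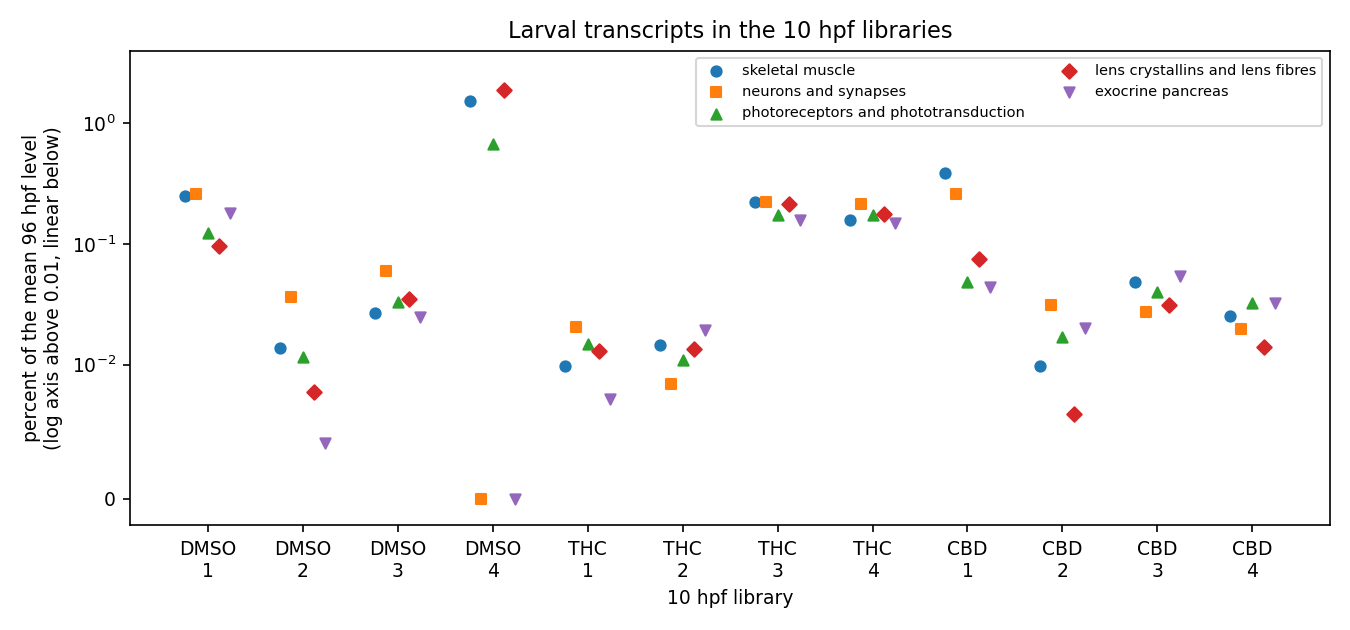
Level of larval transcripts in each 10 hpf library, as a percent of their mean level at 96 hpf (log axis above 0.01, linear below), for 5 lists of genes. THC libraries 3 and 4 hold all lists at like levels (0.224% and 0.171% over all 204 larval genes), DMSO library 1 holds 0.265% and CBD library 1 0.41%, and the shallow DMSO library 4 holds 1.46%, with a count of 0 for neurons and exocrine pancreas.

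Between THC and DMSO at 10 hpf, muscle and stress genes stood lower with THC as groups, and no single gene passed the test. Skeletal muscle genes fell as a list by camera, with 20 of 25 members lower and a median log2 fold change of −0.84 (adjusted p = 4.52e-06), while the adjusted p was 0.949 with an estimated correlation. Without DMSO library 4, which held larval muscle genes at 1.54% of their 96 hpf level, the muscle call was lost (adjusted p = 0.696), and without that library and CBD library 3 together the list pointed up (adjusted p = 0.947). The level of *smyhc1* averaged 0.967 ± 0.790 CPM with THC and 16.8 ± 33.2 CPM with DMSO (SD, n = 4 each), the latter 0.235 CPM without DMSO library 1. Genes of endoplasmic reticulum and integrated stress fell likewise, 16 of 21 lower with a median of −0.16 (adjusted p = 0.00678, and p = 0.8 with an estimated correlation). Among them the chaperone *HSPA5* averaged 199 ± 34.4 CPM with THC and 295 ± 63.4 CPM with DMSO, the unfolded protein factor *XBP1* 288 ± 17.7 and 368 ± 68.3 CPM, and the stress factor *ATF3* 2.38 ± 0.449 and 4.09 ± 2.07 CPM, each with an adjusted p of 1.

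The other lists called lower with THC at 10 hpf moved less evenly. Fibroblast matrix genes had 16 of 21 members lower and a median of −0.54 (adjusted p = 0.0226), erythroid genes 10 of 11 and −0.05 (adjusted p = 0.0437), and epidermal and keratin genes 14 of 23 and −0.05 (adjusted p = 0.047). With an estimated correlation their adjusted p values were 0.949, 0.68 and 0.949. Lens genes were called lower by camera (adjusted p = 0.0338, and p = 0.949 with an estimated correlation), although 9 of 12 members had a positive log2 fold change with a median of 0.19. *FLI1* stood at 0.716 ± 1.12 CPM with THC and 6.69 ± 7.73 CPM with DMSO (log2 fold change −2.70, SE 2.02, adjusted p = 1), and at 0.164 CPM without THC library 4 and 4.16 CPM without DMSO library 4. The smallest p was that of *pak6b*, a kinase gene, at 0.116 ± 0.0870 and 0.601 ± 0.505 CPM (log2 fold change −2.68, SE 0.712, adjusted p = 1). *CNR1*, *CNR2* and *CYP1A1* had too few counts to be tested at this stage.

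The quasi-likelihood test of edgeR called 0 of 17595 genes between THC and DMSO at 10 hpf, with 49 at an unadjusted p under 0.05 where chance alone gives 880, and DESeq2 and voom also called 0. In counts simulated for this comparison, 15.4% of genes changed 4-fold and 0% of those changed 2-fold were recovered. Without DMSO library 4 and CBD library 3 together, the genes called stayed at 0 and 7 lists were called, of which only endoplasmic reticulum and integrated stress was among the 6 above (lower, adjusted p = 0.00106). The others were mitochondrially encoded transcripts (adjusted p = 7.85e-11) and neural plate genes (0.000416), both higher with THC, and p53 targets (0.000416), xenobiotic (0.00146), hepatocyte (0.00252) and intestinal genes (0.0179), all lower. The stress list lost its call without DMSO library 2 (adjusted p = 0.0698). The erythroid, lens, matrix and epidermal calls were each lost without DMSO library 1, DMSO library 4, THC library 1 or THC library 2, and the erythroid and epidermal calls also without THC library 3 (highest adjusted p 0.572, 0.194, 0.705 and 0.602). The erythroid call was lost without DMSO library 2 as well. Between 2 lists (without DMSO library 1 or THC library 1) and 10 lists (without DMSO library 4) were called when a library was left out.

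Between CBD and DMSO at 10 hpf, skeletal muscle genes again stood lower as a list, and single genes did not pass the edgeR test. Of 25 muscle genes 15 were lower, with a median log2 fold change of −0.48 (camera adjusted p = 0.0072, and p = 0.965 with an estimated correlation). The parvalbumin gene *pvalb1* averaged 3.81 ± 4.30 CPM with CBD and 62.9 ± 120 CPM with DMSO (SD, n = 4 each), and *myhz1.1*, a fast myosin heavy chain, 2.66 ± 1.91 and 40.2 ± 73.2 CPM, and the DMSO means were 2.90 and 3.65 CPM without DMSO library 4, where the list pointed up (adjusted p = 0.772). Without CBD library 3 the CBD mean of *pvalb1* was 1.73 CPM. Among the 5 genes with the smallest p were 3 that stood lower with CBD. *RPRD1A*, a regulator of RNA polymerase II, averaged 15.7 ± 1.54 and 28.1 ± 3.12 CPM (log2 fold change −0.84, SE 0.206, adjusted p = 0.805), *ppp2r2aa*, a regulatory subunit of protein phosphatase 2A, 23.0 ± 8.41 and 46.9 ± 8.79 CPM (−1.07, SE 0.274). For *FAM118B* the means were 21.7 ± 5.96 and 42.9 ± 5.58 CPM (−0.94, SE 0.244), and both genes also had an adjusted p of 0.805. *FLI1* stood at 8.20 ± 15.6 and 6.69 ± 7.73 CPM (adjusted p = 0.981), the former 0.399 CPM without CBD library 1 and the latter 4.16 CPM without DMSO library 4.

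The same edgeR test called 0 of 17595 genes between CBD and DMSO at 10 hpf, with 952 at an unadjusted p under 0.05 (880 by chance). DESeq2 called 0, and voom with a quality weight per library called 428, of which 405 were lower with CBD. The weights were 0.286, 2.17, 0.0808 and 0.879 for CBD libraries 1 to 4. For DMSO libraries 1 to 4 they were 0.42, 2.97, 3.26 and 1.01. The voom calls therefore rest mostly on some of the libraries. Without CBD library 1 the edgeR test called 4 genes, all lower with CBD. Without DMSO library 4 and CBD library 3 together it called 0, the muscle list was no longer called (adjusted p = 0.912), and neural plate genes (adjusted p = 0.00747), epidermal genes (0.0221) and mitochondrially encoded transcripts (3.08e-06) were called higher. The muscle list also lost its call without DMSO library 4, CBD library 2 or CBD library 4 (highest adjusted p 0.772). In simulated counts 24.6% of 4-fold and 1.49% of 2-fold changes were recovered.

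Between the cannabinoids at 10 hpf, lists named for gut, liver, skin and hatching gland stood higher with CBD than with THC. The names are those of the lists, and no tissue or cell type is assigned in these whole embryos. The same lists had positive median correlations with the first principal component of 10 libraries of this stage, taken without DMSO library 4 and CBD library 3, which spread within groups. The median was 0.878 for intestine (7 members positive, 1 negative), 0.917 for hepatocytes (18 and 0), 0.668 for epidermis (16 and 7) and 0.912 for hatching gland (4 and 3). CBD library 1 lay at the far end of this component (115.1). All 17 hepatocyte genes were higher, with a median log2 fold change of 1.12 (camera adjusted p = 9.15e-05), and all 7 intestinal genes, with a median of 1.37 (adjusted p = 0.00523), while the adjusted p was 0.949 for both with an estimated correlation. Of their members *apoa2* averaged 143.5 ± 120.9 CPM with CBD and 51.8 ± 26.5 CPM with THC (SD, n = 4 each), *apoa1b* 1952 ± 722.5 and 1141 ± 279.2 CPM, *apoa4b.3* 2.27 ± 1.91 and 0.485 ± 0.212 CPM, and the fatty acid binding gene *FABP2* 309 ± 221.8 and 129.8 ± 88.6 CPM. Without CBD library 1 the CBD means of *apoa2* and *apoa4b.3* were 85.3 and 1.48 CPM, and without THC library 4 the THC mean of *FABP2* was 85.6 CPM. Epidermal and keratin genes were higher for 20 of 23 members, with a median of 0.77 (adjusted p = 9.15e-05, and p = 0.949 with an estimated correlation), among them *cyt1* (481.9 ± 453.5 and 171.9 ± 52.5 CPM) and *krt17* (925.7 ± 918.7 and 393 ± 50.1 CPM). Without CBD library 3 their CBD means were 258.2 and 467.8 CPM. Hatching gland genes were higher for 6 of 7 (median 1.24, adjusted p = 0.0424, and p = 0.949 with an estimated correlation). Their member *he1.1* stood at 41.9 ± 73.5 and 5.40 ± 7.70 CPM, the former 5.24 CPM without CBD library 1 and the latter 1.57 CPM without THC library 4. Xenobiotic genes (17 of 23 higher, median 0.59, adjusted p = 0.0424, and p = 0.949 with an estimated correlation) were called too, with the glutathione transferase *gsta.1* at 23.4 ± 11.7 and 9.17 ± 4.08 CPM. The last call was that of p53 target genes (19 of 21, median 0.30, adjusted p = 0.0445, and p = 0.949 with an estimated correlation), with *rps27l* at 107.1 ± 151.5 and 21.8 ± 8.96 CPM, the former 31.4 CPM without CBD library 3.

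No gene passed the edgeR test between CBD and THC at 10 hpf (0 of 17595, with 1601 at an unadjusted p under 0.05 and 880 by chance). DESeq2 called 0 and voom 719, of which 611 were lower with CBD. Voom gave CBD libraries 1 and 3 low weights here too (0.286 and 0.0808). *nova1*, a neuronal splicing factor, averaged 10.8 ± 5.06 CPM with CBD and 38.9 ± 8.56 CPM with THC (log2 fold change −1.84, SE 0.418, adjusted p = 0.542), and *ppp2r2aa* 23.0 ± 8.41 and 51.4 ± 7.60 CPM (−1.15, SE 0.267, adjusted p = 0.542). Without CBD library 1, 14 genes passed, all lower with CBD, and only the epidermal list was still called. The epidermal list was called whichever library was left out. The hepatocyte and intestinal lists lost their calls without CBD library 1 (adjusted p = 0.185 and 0.199), and the hatching gland, xenobiotic and p53 lists also without CBD library 3 (highest adjusted p 0.185, 0.185 and 0.228). The hatching gland list lost its call without THC library 3 as well, the xenobiotic list without CBD library 4, and the p53 list without CBD library 4, THC library 1 or THC library 4. Without DMSO library 4 and CBD library 3 together the edgeR test called 0 genes and 1 list, that of hepatocytes (adjusted p = 0.000516). In simulated counts 36.4% of 4-fold and 1.49% of 2-fold changes were recovered.

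In larvae at 96 hpf, 11 genes rose with THC against DMSO and 0 fell, among them genes for enzymes and for transporters. *UGDH* (ENSDARG00000019838), which makes the UDP-glucuronate used to conjugate foreign compounds, rose from 34.2 ± 1.2 to 64.8 ± 2.94 CPM (SD, n = 4 each; log2 fold change 0.92, SE 0.0900, adjusted p = 0.0014). *ptgr1.2* (ENSDARG00000087017), a prostaglandin reductase gene, rose from 2.36 ± 1.39 to 23.3 ± 12.9 CPM (3.30, SE 0.429, adjusted p = 0.0226). Among the 11 were 3 genes for transporters of the ATP-binding cassette family. The bile salt export pump *ABCB11* (ENSDARG00000070078) rose from 5.14 ± 1.42 to 12.3 ± 2.48 CPM, *ABCC12* (ENSDARG00000013050) from 8.15 ± 1.63 to 17.4 ± 3.10 CPM and *abcb5* (ENSDARG00000021787) from 71.8 ± 14.1 to 133.7 ± 15 CPM, with log2 fold changes of 1.26 (SE 0.197), 1.09 (SE 0.161) and 0.90 (SE 0.142).

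The other genes that rose with THC included further enzymes. *pon1* (ENSDARG00000032496), a paraoxonase, rose from 14.4 ± 3.18 to 30.0 ± 4.98 CPM, *aifm4* (ENSDARG00000061634), of a family of flavoproteins, from 19.7 ± 6.72 to 45.8 ± 7.94 CPM, and *cbr1l* (ENSDARG00000021149), a carbonyl reductase, from 69.4 ± 5.05 to 119 ± 22.5 CPM, with log2 fold changes of 1.06 (SE 0.165), 1.22 (SE 0.194) and 0.78 (SE 0.124). *PGD* (ENSDARG00000015343), an enzyme of the pentose phosphate pathway, rose from 60.0 ± 3.46 to 92.5 ± 11.3 CPM (0.63, SE 0.0980), and the clone-named genes si:ch211-14a17.10 and si:dkey-286h2.3 by 2.12 and 2.99 on the log2 scale. *PGD* and the clone-named genes are outside the rule that chose the genes to name and were added after their values were seen. For these, the transporters, *pon1*, *aifm4* and *cbr1l* the adjusted p was 0.0404 in edgeR's quasi-likelihood test.

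**Figure D4:**
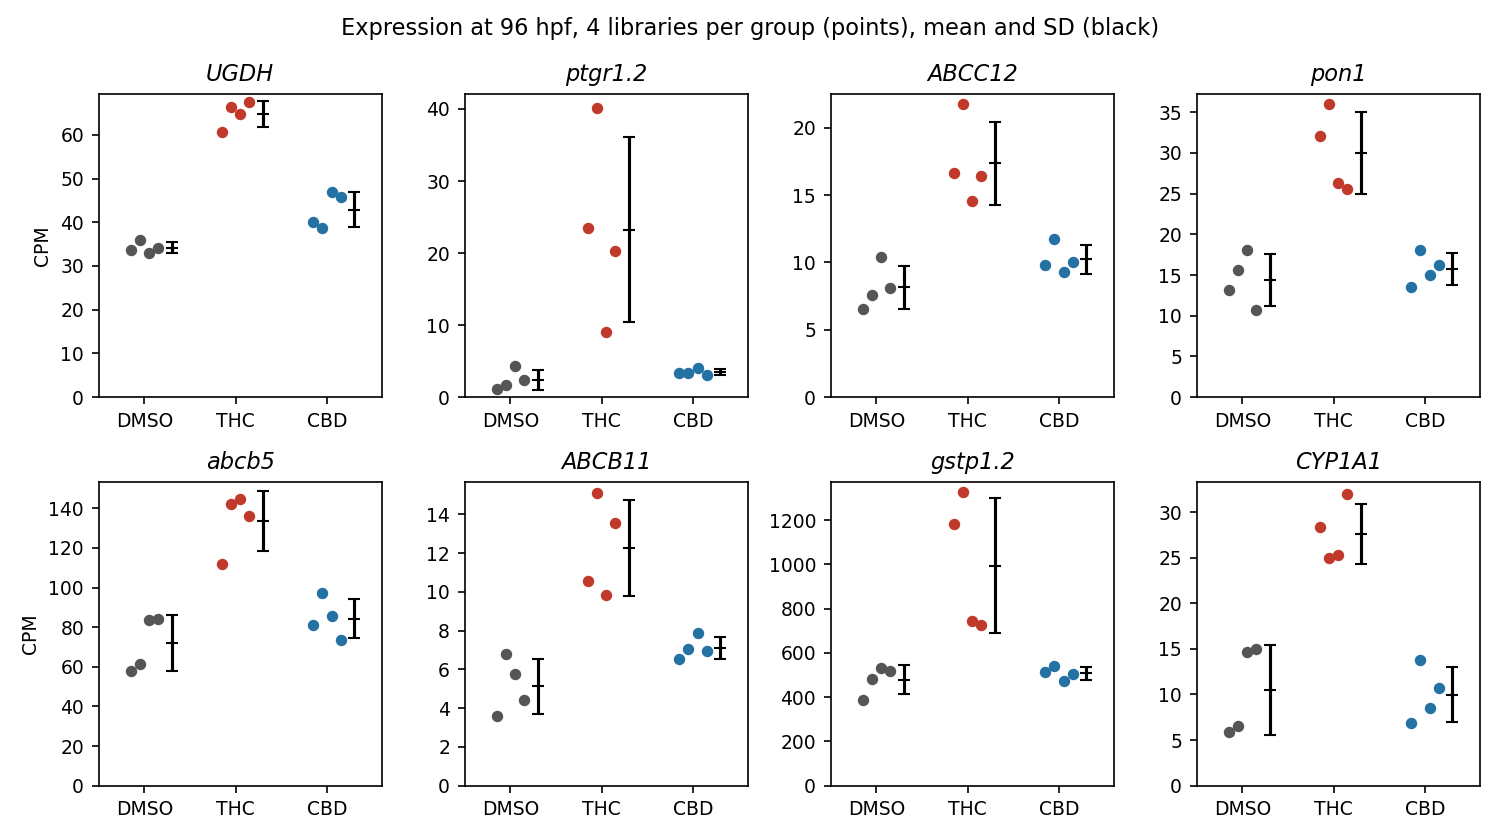
CPM of 8 genes at 96 hpf in larvae raised in DMSO, THC or CBD, with 1 point per library (4 per group) and the mean with SD in black. All 4 THC libraries lie above all DMSO libraries in each panel, which the naming rule required of all but *gstp1.2* and *CYP1A1*. *gstp1.2* and *CYP1A1* did not pass the edgeR test (adjusted p = 0.0838 and 0.213), while DESeq2 called both (5.89e-05 and 0.00205).

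Lists of xenobiotic metabolism and of the oxidative stress response rose with THC at 96 hpf. Both lists hold gstp1, gstp2 and abcc2, and the oxidative stress list shares nqo1 with the aryl hydrocarbon receptor list. These lists are therefore not separate lines of evidence. All 33 tested xenobiotic genes had a positive log2 fold change, with a median of 0.57 (camera adjusted p = 5.96e-25, and p = 0.107 with an estimated correlation). Of them 1 rose over all genes tested by edgeR and 11 adjusted over the list alone. The cytochrome P450 gene *cyp2k18* stood at 16.3 ± 5.33 CPM with THC and 3.81 ± 2.89 CPM with DMSO, the latter 2.37 CPM without DMSO library 3. Its adjusted p was 0.109 by edgeR, 3.13e-05 by DESeq2 and 0.0447 by voom. In the oxidative stress list 25 of 26 were higher, with a median of 0.34 (adjusted p = 3.68e-17, and p = 0.107 with an estimated correlation). By edgeR 0 of them passed the threshold over all genes and 10 adjusted over the list alone. Its leading members were *gstp1.2*, a glutathione transferase (994.2 ± 305.6 and 478.8 ± 65.6 CPM, adjusted p = 0.0838), glutathione reductase *GSR* (52.1 ± 8.89 and 30.7 ± 4.25 CPM, adjusted p = 0.0527). They also included the peroxiredoxin *prdx1* (143 ± 47.6 and 66.1 ± 7.08 CPM, adjusted p = 0.109) and *nfe2l2b*, a zebrafish counterpart of the stress factor NRF2 (9.92 ± 1.94 and 4.96 ± 0.971 CPM, adjusted p = 0.112). DESeq2's Wald test called *gstp1.2*, *GSR*, *prdx1* and *nfe2l2b* over all genes (adjusted p = 5.89e-05, 3.13e-05, 0.000328 and 0.000554), and voom only *GSR* of them (0.0447). Aryl hydrocarbon receptor targets rose as a list with a median of 0.11 (adjusted p = 0.00991, and p = 0.318 with an estimated correlation), 0 over all genes by edgeR and 3 adjusted over the list alone. Without THC library 3 this list lost its call (adjusted p = 0.0947). *CYP1A1*, the classic target of that receptor, stood at 27.6 ± 3.27 and 10.5 ± 4.96 CPM (log2 fold change 1.39, SE 0.288). Its adjusted p was 0.213 by edgeR, 0.00205 by DESeq2 and 0.0447 by voom.

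Gene lists of digestive organs stood higher with THC at 96 hpf, and genes of the lens, skeleton and skin lower. Exocrine pancreas genes had 19 of 20 members higher with a median of 0.84 (adjusted p = 5.42e-10), hepatocyte genes 25 of 26 with a median of 0.23 (1.28e-06) and intestinal genes 15 of 23 with a median of 0.21 (7.92e-05). With an estimated correlation their adjusted p values were 0.426, 0.426 and 0.428. Examples were the carboxypeptidase *CPA1* (ENSDARG00000030915) at 11.8 ± 3.55 and 5.39 ± 4.01 CPM (the latter 3.50 without DMSO library 3), the liver fatty acid carrier *fabp10a* at 330.8 ± 207.8 and 150.5 ± 47.7 CPM and *FABP2* at 283.9 ± 122.1 and 165.8 ± 47.8 CPM. Fatty acid oxidation genes had 21 of 23 members higher (median 0.18, adjusted p = 7.74e-06, and p = 0.34 with an estimated correlation). Lens genes were lower for 21 of 27 (median −0.19, adjusted p = 1.14e-06), neural plate genes for 22 of 24 (−0.13, 7.74e-06), cartilage and bone genes for 24 of 31 (−0.14, 7.92e-05) and fibroblast matrix genes for 20 of 26 (−0.10, 0.000335). Photoreceptor genes were not called, with 27 of 36 higher and a median of 0.14 (adjusted p = 0.0919). The adjusted p values of the 4 lists called lower were 0.426, 0.426, 0.476 and 0.467 with an estimated correlation, and the calls of cartilage and matrix were lost without DMSO library 4 (adjusted p = 0.0807 and 0.227). The lens crystallin *CRYBA1* stood at 2.32 ± 0.378 CPM with THC and 3.60 ± 0.396 CPM with DMSO, the eye field factor *rx3* at 6.79 ± 0.347 and 8.91 ± 0.729 CPM. The cartilage collagen *COL2A1* (ENSDARG00000011407) stood at 663.5 ± 89.6 and 844.7 ± 75.0, *col1a1a* at 2063 ± 163.5 and 2789 ± 348, and the keratin *krt5* at 2108 ± 261.4 and 2946 ± 378.5 CPM. None of these genes was past the threshold over all genes (adjusted p between 0.78 and 1).

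**Figure D5:**
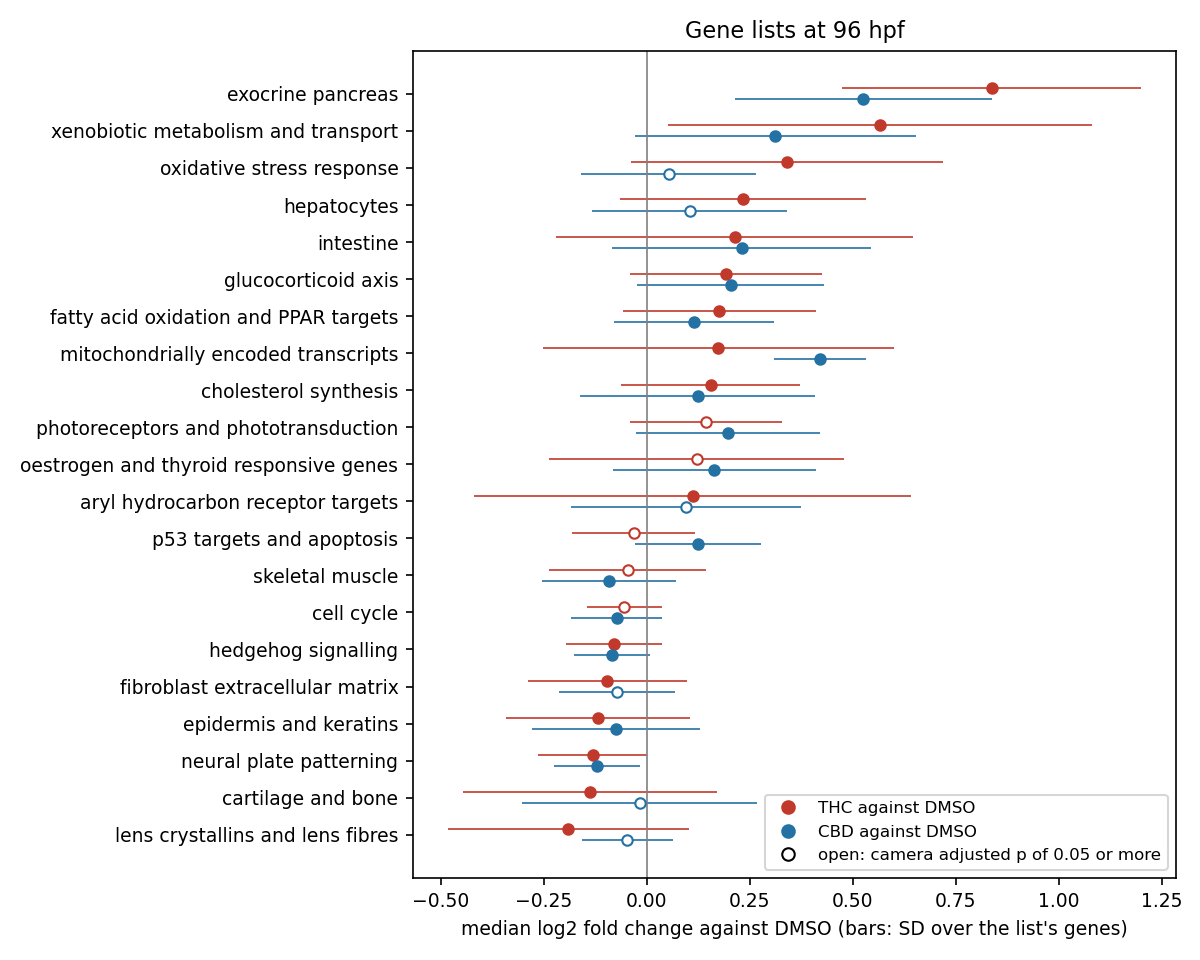
Median log2 fold change against DMSO of 21 gene lists at 96 hpf, for THC (red) and CBD (blue), with bars of 1 SD over the genes of the list, where filled points have a camera adjusted p under 0.05 at the preset correlation and open points do not. Exocrine pancreas lies highest for both (0.84 and 0.53), and the oxidative stress response is filled for THC and open for CBD (0.34 and 0.05).

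A further 5 lists were called between THC and DMSO at 96 hpf and depended on single libraries. Cholesterol synthesis genes were higher (median 0.16, adjusted p = 0.00991, and p = 0.152 with an estimated correlation), but not without DMSO library 2 or THC library 3 (adjusted p up to 0.0947). Glucocorticoid axis genes were higher for 14 of 16 (median 0.19, adjusted p = 0.017, and p = 0.476 with an estimated correlation), with the cochaperone *FKBP5* at 153.6 ± 44.1 and 104.9 ± 25.9 CPM, but not without DMSO library 1, DMSO library 2 or THC library 2 (up to 0.258). Mitochondrially encoded transcripts were higher for 11 of 13 (median 0.17, adjusted p = 0.0419, and p = 0.703 with an estimated correlation), but not without DMSO library 4, THC library 1 or THC library 2 (up to 0.396). Hedgehog genes were lower (median −0.08, adjusted p = 0.0253, and p = 0.563 with an estimated correlation), but not without DMSO libraries 1, 2 or 4 or THC library 2 (up to 0.849). Epidermal genes were lower too (19 of 24 lower, median −0.12, adjusted p = 0.0118, and p = 0.476 with an estimated correlation), but not without DMSO library 4 or THC library 3 (up to 0.361). The cannabinoid receptor gene *CNR1* (log2 fold change 0.15, interval −0.786 to 1.08) and *FLI1* (−0.12, interval −0.507 to 0.272) had an adjusted p of 1, and *CNR2* had too few counts to be tested.

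In the edgeR test behind these calls, 21409 genes were tested between THC and DMSO at 96 hpf, and 802 had an unadjusted p under 0.05 where chance alone gives 1070. DESeq2 called 54 genes (51 higher, 3 lower), among them all 11, and voom 9, of which 5 were among the 11. The fit without a filter called 18, and the fit to only the 8 libraries compared called 1, *UGDH*, with an adjusted p of 0.0217. *UGDH* passed in all 16 alternative settings, with an adjusted p of at most 0.0134 when a library was left out. The count fell to 1 without DMSO library 1, 2 or 4 or THC library 1, to 2 without THC library 2 or 3, and rose to 31 without DMSO library 3. In simulated counts 65.7% of 2-fold and 17.9% of 1.5-fold changes were recovered.

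Between CBD and DMSO at 96 hpf, xenobiotic, pancreatic and mitochondrial genes stood higher with CBD as lists, and no single gene passed the test. Of 33 xenobiotic genes 30 were higher, with a median log2 fold change of 0.31 (camera adjusted p = 1.41e-07, and p = 0.485 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone. The glutathione transferase *gstp1.1* stood at 21.2 ± 9.47 CPM with CBD and 11.1 ± 3.86 CPM with DMSO (SD, n = 4 each), and the cytochrome P450 genes *cyp3c1* and *cyp2k18* at 46.4 ± 3.65 and 33.8 ± 8.19 CPM and at 6.75 ± 1.37 and 3.81 ± 2.89 CPM (2.37 without DMSO library 3). Exocrine pancreas genes were higher for 18 of 20 (median 0.53, adjusted p = 1.93e-07), with the pancreatic disulphide isomerase *pdia2* at 70.4 ± 16.0 and 45.5 ± 27.9 CPM. All 13 mitochondrially encoded transcripts were higher (median 0.42, adjusted p = 1.06e-05), with *MT-ND5* at 966.2 ± 84.5 and 708.5 ± 229.8 CPM. With an estimated correlation the adjusted p of both lists was 0.485. DMSO library 4 held 1.44% mitochondrial counts against 2.94% to 3.84% in the other DMSO libraries, and without it the mitochondrial list lost its call (adjusted p = 0.0667).

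Photoreceptor genes were higher with CBD for 30 of 36 members (median 0.20, adjusted p = 0.000113), with the red opsin *opn1lw1* at 2.45 ± 0.711 and 1.40 ± 0.423 CPM, and neural plate genes lower for 20 of 24 (median −0.12, adjusted p = 7.89e-05), with *SOX2* at 50.9 ± 2.68 and 57.3 ± 3.88 CPM. Both had an adjusted p of 0.485 with an estimated correlation, and both were called whichever library was left out, as were the xenobiotic and pancreatic lists. Higher too were genes of fatty acid oxidation (22 of 23 higher, median 0.12, adjusted p = 0.00242), the glucocorticoid axis (15 of 16, 0.20, 0.00779), cholesterol synthesis (22 of 26, 0.12, 0.0275), oestrogen and thyroid response (11 of 13, 0.16, 0.0307), intestine (17 of 23, 0.23, 0.0275) and p53 targets (17 of 22, 0.12, 0.0388). Lower were skeletal muscle (27 of 34, −0.09, 0.00133), hedgehog (15 of 17, −0.09, 0.0291), cell cycle (23 of 27, −0.07, 0.0291) and epidermal genes (15 of 24, −0.07, 0.0315). With an estimated correlation their adjusted p values lay between 0.485 and 0.879. All 10 of these calls were lost without DMSO library 2, and all but those of skeletal muscle and epidermis also without DMSO library 1. The highest adjusted p with a library left out was 0.125 for fatty acid oxidation and for the glucocorticoid axis, 0.0841 for cholesterol (also lost without DMSO library 3 or CBD library 4), 0.202 for oestrogen and thyroid response (CBD libraries 2 and 4). It was 0.686 for intestine (CBD libraries 3 and 4) and 0.472 for p53 targets (CBD library 1). It was 0.0637 for skeletal muscle, 0.176 for hedgehog (CBD library 2), 0.918 for cell cycle (DMSO library 4, CBD libraries 1 and 2) and 0.474 for epidermis (DMSO library 4, CBD libraries 2 and 3).

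No gene passed the edgeR test between CBD and DMSO at 96 hpf (0 of 21409, with 410 at an unadjusted p under 0.05 and 1070 by chance), and DESeq2 and voom called 0. The genes with the smallest p were *prg4b*, a proteoglycan gene, at 4.69 ± 0.675 CPM with CBD and 2.35 ± 0.580 CPM with DMSO (log2 fold change 1.0, SE 0.230), the complement gene *c4b* at 19.8 ± 5.12 and 9.89 ± 2.47 CPM (1.0, SE 0.245). The others were *asgrl1* at 2.89 ± 0.341 and 1.54 ± 0.366 CPM, the unnamed gene ENSDARG00000106153 at 3.95 ± 1.60 and 1.61 ± 0.527 CPM, and the apolipoprotein B gene *apobb.2* at 4.87 ± 1.55 and 8.64 ± 0.997 CPM, each with an adjusted p of 1. *UGDH* had a log2 fold change of 0.33 (interval 0.136 to 0.520), *CYP1A1* of −0.09 (interval −0.710 to 0.536), *CNR1* of −0.05 and *FLI1* of −0.15, all with an adjusted p of 1. In simulated counts 64.6% of 2-fold and 19.4% of 1.5-fold changes were recovered. In that simulation 124 genes were called, so a change on its own would meet a stricter adjusted threshold.

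The direct comparison of the closed-ring and open-ring cannabinoids at 96 hpf asked whether their effects differ, at doses that are not given in the sources used here. Genes called between THC and DMSO were picked for high values in the same THC libraries, so lower values with CBD follow in part from that choice, and none of them passed the edgeR test between the cannabinoids. The mean of *UGDH* was 42.9 ± 4.05 CPM with CBD and 64.8 ± 2.94 CPM with THC (SD, n = 4 each; log2 difference −0.59, interval −0.785 to −0.403, adjusted p = 0.121), and that of *ptgr1.2* 3.48 ± 0.454 and 23.3 ± 12.9 CPM (−2.73, interval −3.62 to −1.85, adjusted p = 0.121). *pon1* differed by −0.93 (interval −1.29 to −0.580, adjusted p = 0.413), *cbr1l* by −0.68 (adjusted p = 0.441) and *CYP1A1* by −1.48 (interval −2.10 to −0.858, adjusted p = 0.566). DESeq2's Wald test called *UGDH*, *ptgr1.2*, *pon1*, *cbr1l* and *CYP1A1* (adjusted p = 6.61e-07, 3.61e-08, 0.000515, 0.000757 and 0.00102). Of them voom called *UGDH*, *pon1* and *CYP1A1* (0.0496 each), the fit to only the 8 libraries only *CYP1A1* (0.0478), and the fit without a filter only *ptgr1.2* (0.0477). The oxidative stress list was lower with CBD for 23 of 26 members, with a median of −0.28 (camera adjusted p = 5.14e-15, and p = 0.282 with an estimated correlation). By edgeR 0 of them passed the threshold over all genes and 10 adjusted over the list alone. Its members *gstp1.2* and *prdx1* differed by −0.97 and −1.03 (adjusted p = 0.557 and 0.57) and *GCLC*, of glutathione synthesis, by −0.39 (adjusted p = 1). DESeq2 called these members (adjusted p = 0.000757, 0.00287 and 0.0356), and voom did not. Xenobiotic genes were lower for 28 of 33, with a median of −0.34 (adjusted p = 4.57e-09, and p = 0.694 with an estimated correlation), 0 over all genes by edgeR and 6 adjusted over the list alone.

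Other lists were called between the cannabinoids at 96 hpf too. Hepatocyte genes were lower with CBD than with THC for 22 of 26 (median −0.22, adjusted p = 0.000103, and p = 0.694 with an estimated correlation), with transferrin *tfa* at 987.1 ± 189.7 and 1453 ± 191.7 CPM and *serpina1* at 185.3 ± 28.6 and 250.9 ± 9.66 CPM. Cartilage and bone genes were higher for 28 of 31 (median 0.17, adjusted p = 3.86e-05, and p = 0.694 with an estimated correlation), with the cartilage factor *SOX9* (ENSDARG00000043923) at 39.7 ± 4.30 and 32.7 ± 2.77 CPM and the collagen *col9a3* at 408.4 ± 50.4 and 326.7 ± 60.4 CPM. These lists, the oxidative stress list and the xenobiotic list were called whichever library was left out. Lens genes were higher for 23 of 27 (median 0.17, adjusted p = 4.19e-05, and p = 0.694 with an estimated correlation), but not without THC library 3 (0.308). Acute inflammation genes were higher for 19 of 20 (median 0.38, adjusted p = 0.0013, and p = 0.742 with an estimated correlation), but not without CBD library 1 (0.406), which held the cytokine gene *il1b* at 4.28 CPM where the means were 1.80 ± 1.67 (0.969 without it) and 0.648 ± 0.176 CPM. The itaconate gene *irg1l* stood at 54.2 ± 16.6 and 20 ± 13.3 CPM.

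Weaker list calls between CBD and THC were p53 targets (19 of 22 higher, median 0.12, adjusted p = 0.022), cardiac muscle (14 of 19 higher, 0.11, 0.022), with the natriuretic peptide *nppa* at 6.48 ± 1.64 and 4.61 ± 1.63 CPM, mitochondrially encoded transcripts (13 of 13 higher, 0.18, 0.0306) and skeletal muscle (30 of 34 lower, −0.10, 0.0229). With an estimated correlation their adjusted p values were 0.694, 0.694, 0.742 and 0.742. Leaving out CBD library 1, THC library 3 or THC library 4 ended the p53 call (up to 0.362), CBD library 4 or THC library 2 the cardiac call (up to 0.337). Leaving out CBD library 1 or 3 or THC library 3 or 4 ended the mitochondrial call (up to 0.447), and CBD libraries 2 to 4 or THC library 1 or 2 the skeletal muscle call (up to 0.559). The edgeR test called 0 of 21409 genes between CBD and THC at 96 hpf, with 540 at an unadjusted p under 0.05 (1070 by chance). DESeq2 called 14 genes, all lower with CBD, voom 3, the fit without a filter 1, the fit to only the 8 libraries compared 3, and the fit without THC library 3 1. In simulated counts 62.7% of 2-fold and 14.9% of 1.5-fold changes were recovered.

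Whether an effect differed between 10 and 96 hpf was tested as an interaction. Among the 5 genes with the smallest p for THC, the effect on *UGDH* was larger at 96 hpf by 1.0 on the log2 scale (SE 0.25, adjusted p = 1). The effect on *cyp2k18* was larger by 3.23 (adjusted p = 1). For the THC effect 0 of 22741 genes passed the edgeR test (539 at an unadjusted p under 0.05, smallest adjusted p 1), and for the CBD effect 0 (1523, smallest adjusted p 0.715). DESeq2 called 0 for both. Without CBD library 1 of 10 hpf 4 genes passed for CBD, and without DMSO library 4 and CBD library 3 of 10 hpf together 1 gene passed for THC. A call in larvae with none at 10 hpf is therefore not shown to be a difference between the stages. Stage and length of exposure also cannot be told apart in this test.

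THC and CBD effects were compared across genes, which are not independent replicates and here share their DMSO libraries. At 96 hpf the log2 fold changes of both against DMSO had a Pearson correlation of 0.486 over 21409 genes, and a covariance of 0.0293. Unchanged groups simulated with shared controls, themselves drawn anew, gave 0.498 and 0.0342. With the controls split into sets of 2 libraries the correlation averaged −0.107 (from −0.322 to 0.059). At 10 hpf it was 0.038 beside a simulated 0.562, with a covariance of 0.00827 beside 0.189, and averaged −0.362 with split controls. It was 0.624 without DMSO library 1 and 0.368 without CBD library 1. The simulations drew each gene apart and without the structure of the samples, and ranged from 0.547 to 0.579 at 10 hpf and from 0.479 to 0.51 at 96 hpf. Leaving out 1 real library gave −0.092 to 0.624 and 0.381 to 0.694, so the gaps to the simulated values decide nothing about the cannabinoids. At an unadjusted p under 0.05, 104 genes were higher and 20 lower with both cannabinoids at 96 hpf, where independent lists give 8.21 and 1.11 and the simulated shared controls 221 in all, and 0 genes passed the adjusted test in both.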

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

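The tests of explanations in this part were chosen only after the results were seen. The library with the most distant value in each group of 4 was tested with Dixon's ratio at its 95% critical value, which chance passes in about 1 in 20 groups.

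Among quality measures 3 of 30 groups passed, where 1.5 were expected. DMSO library 4 of 10 hpf passed for total counts (ratio 0.934, 125926 counts) and for genes with a count (0.914, 10045 genes), and DMSO library 3 of 96 hpf for the share of the top 10 genes (0.835, 10.4%). Among the genes named at 96 hpf 9 of 156 groups passed, where 7.8 were expected: *prdx1* in CBD library 1 (0.934), *nfe2l2b* in THC library 2 (0.833), *cyp2k18* in DMSO library 3 (0.876), *COL2A1* in DMSO library 4 (0.936), *apobb.2* in THC library 2 (0.836), *cyp3c1* in THC library 2 (0.846), *pdia2* in DMSO library 3 (0.84), *il1b* in CBD library 1 (0.854) and *col9a3* in DMSO library 4 (0.941).

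Among 21 of the genes named at 10 hpf 16 of 63 groups passed, where independent groups would give 3.15. Genes that move together do not give independent groups. *smyhc1* and *he1.1* are also among the markers that set these libraries apart above, so their flags add nothing to that. DMSO library 1 passed for *smyhc1* (0.993), *apoa2* (0.885), *FABP2* (0.964) and *he1.1* (0.976), and CBD library 1 for *smyhc1* (0.995), *FLI1* (0.979) and *he1.1* (0.941). THC library 4 passed for *FAM118B* (0.855), *FABP2* (0.932), *cyt1* (0.875) and *he1.1* (0.888). CBD library 3 passed for *XBP1* (0.845), *krt17* (0.91) and *rps27l* (0.971), and DMSO library 4 for *pvalb1* (0.975) and *myhz1.1* (0.947).

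The spread of 10 hpf libraries along their first principal component (59% of variance, 10 libraries) could come from embryos at different points of development, from larval material carried over, or from treatment. Maternal genes had a median correlation of −0.884 with it (20 of 21 negative), which fits embryos at different points, though the genes themselves make this component and no p is given. Carry-over was first tested on the hatching gland list, which was void because this list stood at 96.9% to 253% of its 96 hpf level in all 10 hpf libraries. The maternal genes tested in its place, once this was known, differed between the ends of the component by a median log2 of −1.56, and carry-over of at most 0.41% cannot lower them so. Treatment groups held 0.122 of the variance along it, where random groups hold 0.22 on average, which argues against treatment as its main source. A smaller shift with treatment, within the spread of these 10 libraries, stays open.

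Larval transcripts in 10 hpf libraries, at 1.46% of their 96 hpf level in DMSO library 4, 0.41% in CBD library 1, 0.265% in DMSO library 1 (the cause in these last libraries was not tested), 0.224% in THC library 3 and 0.171% in THC library 4, could be larval material carried over, more advanced embryos, or a like number of stray reads in every library. In THC libraries 3 and 4 the highest list share was 1.42 and 1.45 times the lowest, which fits carry-over. The lower of their larval counts was 6.89 times the median of the 10 hpf libraries, which argues against a like number there. The ratio of highest to lowest list share was 2.68 in DMSO library 1 and 8.88 in CBD library 1, so their lists stood at less even shares. In DMSO library 4 *smyhc1* had 0 counts where the levels of DMSO library 1 and CBD library 1 give 9.37 and 21.2 (exact one-sided Poisson p = 8.55e-05 and 6.12e-10), which argues against embryos like those, while the levels of THC library 4 and CBD library 2 give too few to decide (0.239 and 0.0269, highest exact p = 0.974), so embryos advanced in another way stay open there. Its 319 larval counts were 0.332 of the median, where 6.27 were expected from its depth, and a like number of stray reads could neither be shown nor excluded there.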

How the results depend on the processing

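With an estimated correlation and with the directional test of fry, 0 lists were called in each of the 6 comparisons (6, 1, 6, 16, 15 and 10 at the preset correlation). Fry's test of changes in either direction passed at 96 hpf for aryl hydrocarbon receptor targets, xenobiotic metabolism and oxidative stress between THC and DMSO (adjusted p = 0.00266, 0.0188 and 0.00266) and for oxidative stress between CBD and THC (adjusted p = 0.0219). Voom with library weights called 428 genes for CBD against DMSO and 719 for CBD against THC at 10 hpf, and 3 for CBD against THC at 96 hpf, all moved from 0. Without DMSO library 4 and CBD library 3 of 10 hpf, lists moved to 3 for CBD against DMSO, were weaker at 1 for CBD against THC, and the stage difference for THC moved to 1 gene.

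For THC against DMSO at 96 hpf, 11 genes became 18 without a filter and 54 with DESeq2, 1 with the replicate number as a block and 1 with only the 8 libraries compared. For CBD against THC at 96 hpf, 0 became 1 without a filter, 14 with DESeq2 and 3 with only the 8 libraries. Replicate numbers were not taken to pair the libraries, because correlations of same-number libraries were over 0.1 in only 4 of 12 pairs at 10 hpf (−0.545 to 0.653) and 7 of 12 at 96 hpf (−0.25 to 0.402). At 96 hpf their median was 0.141 against −0.097 for other pairs, and 6 of 12 libraries correlated best with their own number (2 of 12 at 10 hpf), so a partial sharing by number is not excluded. The cause of these moves was not tested.

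Leaving out 1 library at a time gave, for THC against DMSO, CBD against DMSO and CBD against THC, 0–0, 0–4 and 0–14 genes and 2–10, 0–4 and 1–9 lists at 10 hpf, and 1–31, 0–0 and 0–1 genes and 11–21, 7–16 and 9–14 lists at 96 hpf. Stage differences gave 0–0 for THC and 0–4 for CBD, and the correlation of effects −0.092–0.624 at 10 hpf and 0.381–0.694 at 96 hpf. Over 4318 gene settings 4185 were the same, 89 weaker, 44 stronger and 0 reversed, and 23 of 254 uncalled genes and 0 of 11 called ones changed sign in a setting. Most of the same were uncalled genes that stayed uncalled, and all 89 weaker were lost calls of the 11. Of these, *UGDH* kept its call in 16 of 16 settings, *ptgr1.2* in 9 of 16 and si:dkey-286h2.3 in 4 of 15. The others kept theirs in 6 to 8 of 16.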

Other observations

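The tests of explanations in this part were chosen only after the results were seen. Lists of direct interest that were not called at 96 hpf showed small medians. Endocannabinoid genes had a median log2 fold change of 0.07 for THC and 0.02 for CBD against DMSO (camera adjusted p = 0.32 and 0.789), and endothelial genes, the tissue marked in this line, −0.02 and −0.01 (0.361 and 0.837). Neuronal genes had medians of −0.03 and 0.04 (0.294 and 0.56), heat shock genes 0.02 and −0.06 (0.999 and 0.0644), and retinoic acid genes 0.00 and −0.01 (0.329 and 0.63). Oxidative stress genes had a median of 0.05 for CBD (0.178).

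The genes higher with THC at 96 hpf could reflect a larger share of digestive organs, the structure that parts libraries 1 and 2 from 3 and 4, or depth. Hepatocyte and intestinal genes had medians of 0.234 and 0.213 against 1.09 for the 11 genes, which were picked for large rises in these libraries. Lower medians follow in part from that choice, so this comparison cannot decide against a larger share of these organs. Exocrine pancreas, tested after its value was seen, stood at 0.837 and stays open too. With the structure as a term by library number 11 of 11 genes were kept, but each group has as many libraries on either side by number. The design so keeps the folds and this decides nothing. On the first principal component of 96 hpf CBD library 2 (23.7) lay with CBD libraries 3 and 4 (14.1 and 7.1). The term therefore did not follow that component in CBD. At a common depth of 14879976 counts only 2 of the 11 passed, which by the bound first set would have pointed to depth, but that bound was wrong because most of the genes shared an adjusted p of 0.0404, close to the threshold. The test was then posed anew on folds, where 10 genes were tested again with a median log2 of 1.07 (SE 0.16) before and 1.03 (SE 0.16) after. Random thinning keeps the expected folds whatever the cause, so this cannot decide about depth. The median p was 1.62e-05 before and 1.51e-05 after by edgeR. Only the median adjusted p crossed the threshold (0.0404 and 0.0565), in 1 thinning over 20630 genes. Before thinning, library totals averaged 22198012 ± 2489226 counts with DMSO and 21638221 ± 4550829 with THC (SD, n = 4 each). The groups so did not differ in depth beyond their spread, which argues against a depth difference as the source of these rises.

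Whether chance could make results as large was tested by other splits of the libraries. It cannot be excluded for the genes called between THC and DMSO at 96 hpf, where 3 of 35 splits were as large (real 11, highest other 2832). That split sets libraries 1 and 2 against 3 and 4 and points to a structure of the samples. Where the real count was 0, every split is as large by construction and nothing follows about chance. This holds at 10 hpf for THC against DMSO, CBD against DMSO and CBD against THC (35, 35 and 35 splits, highest others 0, 1185 and 1), and at 96 hpf for CBD against DMSO and CBD against THC (35 and 35, highest others 2 and 0). It holds too for the stage differences of THC and CBD (40 and 40, highest others 2 and 2591). The split with 1185 genes, which sets CBD libraries 1 and 2 with DMSO libraries 1 and 4, and that with 2591 also point to a structure of the samples.

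Chance cannot be excluded for the number of lists called. At 10 hpf 14, 35 and 24 of 35 splits were as large for THC against DMSO, CBD against DMSO and CBD against THC (real 6, 1 and 6, highest others 14, 9 and 14), and at 96 hpf 9, 8 and 17 (real 16, 15 and 10, highest others 19, 22 and 17). The cause of the structure in the samples was not tested.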
